A study of Mus musculus with 4 samples.

How the data were processed

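The samples were 4 libraries of cells sorted for CD45 from subcutaneous CT26 tumours in mice, made with the 10x Chromium 3' v3 chemistry per the labels. Tumour cells were control cells or cells treated with 25 nM flavopiridol for 7 days before injection, and mice received IgG or anti-CTLA4. Each of the 4 groups held 1 library, and the number of animals behind a library is not given in the sources used here. The deposited values are raw counts, whole numbers of UMIs per gene and barcode for 27998 genes in barcodes already called as cells, with no normalization. The authors name Cell Ranger, listed as 1.3, and Seurat in their processing notes, without a role for each. Genome build and annotation are not given in the sources used here, and gene symbols were taken as they stood.

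Barcodes with at least 200 genes and at most 15% mitochondrial UMIs were kept, which left out 118, 236, 167 and 210. A doublet score was computed in each library with scanpy 1.11.5, and the highest-scoring barcodes were left out at 0.8% per 1000 barcodes, which took 339, 476, 443 and 649. Counts were scaled to 10000 per cell and log-transformed, and all libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours at Leiden resolution 1.0. T and NK cells (TNK clusters) and monocytes and macrophages (MM clusters) were clustered again on their own, for 47 clusters in all. Python 3.11.15 ran numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 ran edgeR 4.0.16 and DESeq2 1.42.0.

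Clusters were named from 22 marker sets fixed before the data were examined, by the set with the highest mean score, and are called "X-like". Markers missing among the genes were Trac, Trbc2, Trdc, Trdv4, Tcrg-C1, Tcrg-C2, Ighm, Ighd, Igha, Ighg1, Ighg2b and Iglv1, so gamma-delta T-like cells rest on few markers, among them Cd163l1 and Il17a. Thresholds of naming were set while the clusters were looked at: a score of at least 0.35 with at least 3 markers each detected in 10% of the cells, a score of at least 0.5 for a T class, and no type 2 innate lymphoid name among T and NK clusters. A name was dropped where another class had as many markers among the cluster's 10 leading genes, or where none of its own were there and UMIs per cell were under the library median divided by 3. Neutrophil-like cluster 12 had none of its own there and UMIs at that limit. Unnamed clusters with a Ptprc UMI in under 20% of cells are called Ptprc-low, and the rest of the unnamed clusters stayed so.

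A share is the number of cells of a class over all kept cells of the library, with an exact binomial 95% interval, and groups are compared by the ratio of shares with an exact conditional interval. For gene levels, raw counts were summed over the cells of a class in each library and scaled to the class total (CPM). Log2 ratios carry exact conditional 95% intervals for counting error, without the spread between cells or animals. A count of 0 would take a floor of 3 counts. Comparisons were flavopiridol against control tumours within IgG and within anti-CTLA4, and anti-CTLA4 against IgG within control and within flavopiridol tumours. No test was made for any of them, because each group had 1 library and cells are not replicates. A fit of the 2 main effects over the 4 libraries, without their interaction, was not made.

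Named genes followed a rule fixed before the data were examined. In each of the 3 largest named classes with at least 100 cells in every library (NK-like, neutrophil-like and CD4 T-like), genes with a log2 ratio of the same sign in both arms were ranked by the smaller of the 2 ratios. The 6 highest and 6 lowest were named for flavopiridol and 4 each way for anti-CTLA4, with at least 50 CPM in the higher library and 50 summed counts in both arms. Left out were mitochondrial, ribosomal, immunoglobulin, T cell receptor segment, haemoglobin, Y-linked and model genes, Xist, and genes 10-fold below their level in another class, which free RNA can bring. Genes that passed numbered 1622, 1090 and 1926 for flavopiridol and 1218, 1001 and 1167 for anti-CTLA4. Macrophage-like cells (1826 and 1634 genes) and the Ptprc-low clusters (1718 and 1276), which hold more cells than the CD4 T-like class but no cell type name, were added by the same rule after the data had been seen. Up to 4 members of each list, those with the most counts, and Ctla4, Foxp3, Cd274 and Pdcd1 were also looked at.

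The 21 gene lists, fixed before the data were examined, were type I interferon response, interferon gamma response, NF-kB inflammatory response, nucleic acid sensing, myeloid suppressor, alternative macrophage activation, lipid handling and phagocytosis, glycolysis and hypoxia, MHC class I and class II presentation, dendritic cell co-stimulation, chemokines, cytotoxic effector, T cell exhaustion, naive and memory T cell, Treg activation, NK activation and inhibition, neutrophil granule and activation, proliferation, dissociation stress and a sex-linked check. Members not found among the genes were Calhm6, Cgas, Sting1, Rigi, Selenop, Ero1a, Cd244a and Pclaf. A list's value is the median log2 ratio of members with at least 20 summed counts, with an interval from 2000 Poisson draws and a percentile among 10000 random lists that draw each member from the 100 genes nearest in level. Of 1105 medians over all classes, 142 are reported, for 48 of 302 pairs of list and class chosen after the medians had been seen and before their alternatives were computed.

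The calculation of the gene comparison was tested on simulated Poisson counts: 4 libraries drawn from the pooled NK-like profile with 200 of 27998 genes altered in the flavopiridol groups. Within IgG, simulated log2 folds of 1, -1, 2 and -2 came back with medians of 0.96, -1.05, 1.95 and -2.07, and 98%, 96%, 92% and 94% of intervals held the simulated ratio, as did 95.6% of those of 9392 unaltered genes. The 12 genes named by the rule were all altered genes. Besides library depth, precision is given per class as the widest factor from a named fold to its counting bound. It was 1.07 for Ptprc-low clusters and 1.78 for neutrophil-like cells. The simulated counts had no spread between cells, so that spread is untested. Alternatives covered the filters, doublets, clustering resolution, naming by cell or by library, denominators, 2 other scalings of totals, means over cells and count minimums.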

Results

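The data were single-cell RNA profiles of cells sorted for CD45, the surface protein encoded by Ptprc that marks white blood cells, from subcutaneous tumours of CT26, a mouse colon carcinoma line. Before injection the CT26 cells had been left as controls or grown for 7 days in 25 nM flavopiridol, a drug that inhibits several cyclin-dependent kinases, among them CDK9, the kinase that releases RNA polymerase II into elongation. Mice then received a control IgG or an antibody against CTLA4, an inhibitory receptor of T cells. These choices gave 4 groups with 1 library each: control tumours with IgG, flavopiridol tumours with IgG, control tumours with anti-CTLA4 and flavopiridol tumours with anti-CTLA4, the order in which 4 values are given below. The libraries held 6571, 7835, 7522 and 9114 barcodes with 93555142, 95635266, 98895025 and 127298877 UMIs (counted RNA molecules), and medians of 5622, 4990, 5615.5 and 6155.5 UMIs per barcode. After filtering, 6114, 7123, 6912 and 8255 cells were kept. With 1 library per group no difference was tested between groups. Values have 95% intervals for counting error only, which leave out the spread between mice and, for genes, between cells.

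The first comparison asked how the immune infiltrate differed between flavopiridol and control tumours. T-like cells made up more of the infiltrate of flavopiridol tumours under both antibodies. CD4 T-like cells, named by Cd4, Cd40lg and Icos beside Cd3d and Cd3e, were 24.5% (23.5 to 25.5) of kept cells in the flavopiridol tumour with IgG against 8.55% (7.86 to 9.28) in the control tumour, a ratio of 2.86 (2.59 to 3.16). With anti-CTLA4 they were 14.96% (14.2 to 15.7) against 6.09% (5.54 to 6.68), a ratio of 2.46 (2.20 to 2.75). Gamma-delta T-like cells, which expressed the interleukin gene Il17a and the scavenger receptor gene Cd163l1, showed ratios of 3.46 (2.89 to 4.17) and 4.51 (3.60 to 5.72), from shares of 2.42%, 8.38%, 1.302% and 5.88%. Treg-like cells, marked by Foxp3, the transcription factor of regulatory T cells, were 2.13%, 4.39%, 1.40% and 1.55% of cells, with ratios of 2.07 (1.68 to 2.56) within IgG and 1.10 (0.842 to 1.45) within anti-CTLA4. All named T-like classes together took 13.1%, 38.5%, 17.8% and 25.8% of cells, ratios of 2.94 (2.71 to 3.18) and 1.45 (1.35 to 1.55), and all clusters with T cell genes, named or not, 17.8%, 41.7%, 19.6% and 27.1%. Within T clusters the gamma-delta markers were also higher in flavopiridol tumours, with Il17a at 63.2, 137, 52.7 and 98.8 CPM (counts scaled to a common class total) and Cd163l1 at 124, 226, 48.1 and 132. CD4 T-like ratios depended on naming, being 0.895 and 0.103 with each library clustered on its own. All T-like cells together then had ratios of 2.32 and 1.33. Those ratios count in 0, 740, 0 and 1001 cells of T clusters given no T class, so they rest in part on cells outside the named classes. The Treg-like ratio within anti-CTLA4 was 1.88 when each cell was named by its own markers.

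**Figure D1:**
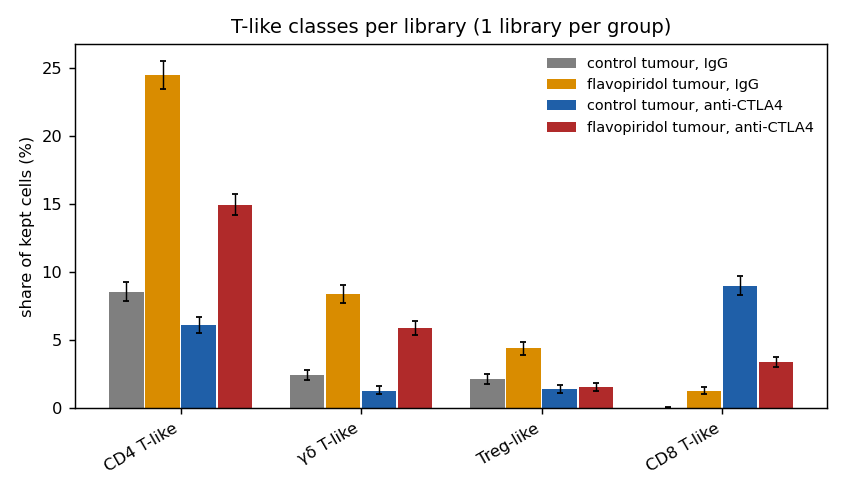
Shares of kept cells (percent) of 4 T-like classes, with 1 bar per library in the 4 groups; error bars are 95% exact binomial intervals for counting error. CD4 T-like and gamma-delta T-like bars stood higher in flavopiridol tumours under both antibodies, while CD8 T-like cells reached 8.999% in the control tumour with anti-CTLA4.

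CD8 T-like cells, the class of cytotoxic T cells named by Cd8a and Cd8b1, went opposite ways under the antibodies. With IgG they numbered 90 cells or 1.26% (1.02 to 1.55) in the flavopiridol tumour and 1 cell or 0.0164% (0.000414 to 0.0911) in the control tumour, a ratio of 77.3 (13.5 to 3085) that rests on that 1 cell. With anti-CTLA4 they were 3.38% (3.00 to 3.79) in the flavopiridol tumour and 8.999% (8.33 to 9.70) in the control tumour, a ratio of 0.376 (0.325 to 0.433). In the class, TNK17, led by Cd8a and Ifng, held 0, 47, 145 and 260 cells, a higher share in flavopiridol tumours under both antibodies. Only TNK19, led by Nrn1 and Cd8b1, went opposite ways, with 1, 43, 477 and 19, 88.3% of them from 1 library. Over the cells of all T clusters, whatever their names, Cd8a stood at 23.1, 114, 537 and 260.0 CPM and Cd8b1 at 34.9, 135, 564 and 265. Thinned to 2000 UMIs per cell, 4.63%, 10.0%, 52.7% and 16.4% of T-cluster cells had a Cd8a or Cd8b1 UMI, with 162, 287, 154 and 338 shallower cells left out. Without thinning the shares were 6.79%, 12.2%, 51.3% and 17.8%. NK-like cells, which should lack both genes, had 0.189%, 0.804%, 0.386% and 0.318% when thinned. Median depths were 3491.5, 3818, 4905 and 3333 UMIs in T clusters and 5159, 6499, 4774 and 8872 in NK-like cells. CD8 T-like cells per Treg-like cell were 0.00769 (0.000193 to 0.0436), 0.288 (0.225 to 0.365), 6.41 (5.17 to 8.03) and 2.18 (1.76 to 2.71). Named from each cell's own markers the CD8 T-like ratio within IgG was 5.41, and with libraries clustered on their own 1.74.

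Among the other classes, neutrophil-like cells (S100a8, S100a9 and Csf3r) were lower in flavopiridol tumours, at 18.7%, 10.9%, 25.5% and 18.4%, ratios of 0.584 (0.532 to 0.640) and 0.720 (0.672 to 0.771). NK-like cells, natural killer cells named by Ncr1 and the Klr receptors, were 19.0%, 18.7%, 17.1% and 23.6%, so that the ratio was 0.984 (0.909 to 1.07) within IgG and 1.38 (1.28 to 1.48) within anti-CTLA4. Macrophage-like cells, marked by C1qa, Apoe and Adgre1, were 8.67%, 5.56%, 8.23% and 10.9%, with a lower share in the flavopiridol tumour within IgG, 0.641 (0.562 to 0.732), and a higher one within anti-CTLA4, 1.32 (1.19 to 1.47). Conventional dendritic-like cells, which present antigen to T cells, were 3.65%, 1.35%, 1.32% and 0.921%, ratios of 0.370 (0.288 to 0.471) and 0.699 (0.509 to 0.959), and monocyte-like cells 6.46%, 4.67%, 2.26% and 2.29%, ratios of 0.724 (0.624 to 0.839) and 1.01 (0.816 to 1.26). B-like cells were 1.44%, 1.31%, 1.71% and 0.678%, ratios of 0.907 (0.670 to 1.23) and 0.397 (0.284 to 0.551). Mast or basophil-like cells were 1.16%, 0.772%, 0.304% and 0.339%, plasmacytoid dendritic-like cells 0.393%, 0.463%, 0.275% and 0.145% and migratory dendritic-like cells 0.262%, 0.295%, 0.145% and 0.279%. Fibroblast-like cells were 0.180%, 0.0562% and 0.492% in the first 3 groups and 0 of 8255 cells in the last, with an interval that reaches 0.0447%. Clusters left unnamed held 6.28%, 4.97%, 5.48% and 2.23% of cells, among them TNK9, led by Calca, Penk, Il4 and Il13, at 3.11%, 0.0983%, 0.188% and 0.0363%. Some clusters had a Ptprc UMI in under 20% of their cells although the sort was for CD45, and these Ptprc-low clusters, with median depths of 41429.5, 55948.5 and 19867 UMIs, held 20.7%, 12.4%, 19.3% and 14.5%, ratios of 0.601 (0.551 to 0.655) and 0.750 (0.693 to 0.812). The neutrophil-like share lies near the filter on genes, with 44.3%, 22.2%, 43.5% and 22.9% of its cells under 500 genes. Its ratio within anti-CTLA4 turned above 1 at 10% mitochondrial UMIs (1.52), with no barcodes left out as doublets (1.34) and without cluster 12 (1.23). Under those mitochondrial and doublet settings, neutrophil-like cells of the control tumour with anti-CTLA4 fell from 1766 to 666 and 844. Unnamed cells there rose from 379 to 1437 and 1449, so naming changed with the filter. Cluster 12 had none of the neutrophil markers among its 10 leading genes. The macrophage-like ratio within anti-CTLA4 turned below 1 at 500 genes per barcode (0.748) and with no barcodes left out as doublets (0.980). The conventional dendritic-like ratios were 0.660 and 1.01 when each cell was named by its own markers, and the first was 0.631 with libraries clustered on their own.

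**Figure D2:**
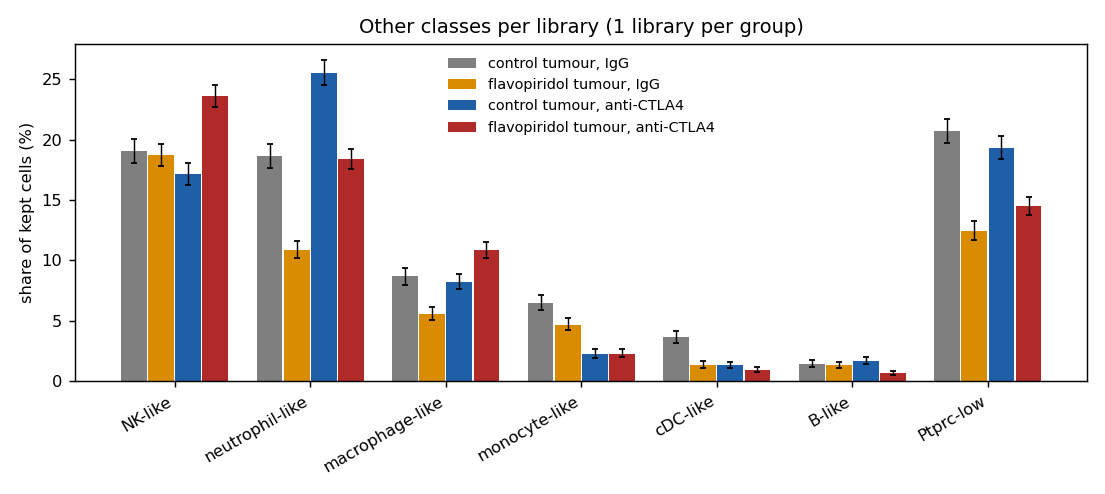
Shares of kept cells (percent) of NK-like, myeloid-like and B-like classes and of the Ptprc-low clusters, with 1 bar per library in the 4 groups and 95% exact binomial intervals for counting error. Neutrophil-like bars stood lower in flavopiridol than in control tumours under both antibodies, at 10.9% against 18.7% and 18.4% against 25.5%.

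Within CD4 T-like cells, proliferation genes were lower in flavopiridol tumours and dissociation stress genes higher, as the lists below show. TNK6 was the largest CD4 T-like cluster in every library, with 60.6%, 57.9%, 51.3% and 66.6% of the class. TNK15, led by Il13, Mki67 and Fabp5 among others, held 42 of 523, 77 of 1743, 42 of 421 and 42 of 1235 CD4 T-like cells, and TNK11 held 10, 109, 10 and 65. A different mix of these clusters stays open as a source of the differences below. Folds are given within IgG and then within anti-CTLA4. Il2, the T cell growth factor, was 36.6 and 28.4-fold lower, but 5 cells held 97.9% and 95.1% of its counts in the control libraries. Without the top 5 cells of each library Il2 stood at 5.29, 5.33, 5.93 and 2.77 CPM, so most of its fold rests on those cells. Il4, a T helper cytokine, was 2.50 and 3.00-fold lower and Fabp5, a fatty acid binding protein, 5.44 and 3.91-fold lower. In control tumours 5 cells held 33.7% and 66.5% of the Il4 counts and 26.4% and 54.6% of those of Fabp5. Without the top 5 cells of each library, Il4 stood at 86.9, 47.5, 62.0 and 51.3 CPM and Fabp5 at 956, 221, 433 and 207. Hmgn2 and Hmgn1, which bind nucleosomes, were 2.28 and 2.90-fold and 2.28 and 2.59-fold lower and Cks1b, a partner of cyclin-dependent kinases, 2.20 and 3.33-fold lower. Fosb, an early-response transcription factor, was 2.70 and 2.82-fold higher, from 150.4 (135 to 167) to 406 (391 to 420.0) CPM within IgG. Higher too were Stk32c, a kinase (2.26 and 2.41-fold), Fam46a (2.10 and 6.24-fold), the membrane protein Emp1 (3.08 and 2.10-fold), AY036118 (2.09 and 5.08-fold) and Nrgn, a calmodulin binding protein (3.48 and 2.17-fold). Of the Nrgn counts, 5 cells held 72.0%, 27.4%, 42.0% and 33.1%, and without the top 5 cells Nrgn stood at 9.27, 83.6, 27.5 and 68.7 CPM, a wider gap within IgG. Nrgn also leads the CD8 T-like clusters, Il2 the CD4 T-like cluster TNK11 and Fabp5 the CD4 T-like cluster TNK15. At 500 genes per barcode Nrgn was lower under both antibodies (-0.37 and -0.92, log2), and it was lower within anti-CTLA4 (-1.51) with no barcodes left out as doublets. The 12 folds had counting bounds within a factor of 1.67, the widest being that of Il2.

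Gene lists fixed in advance are given as the median log2 ratio of their measured members, with the counting interval of that median, and its percentile among 10000 random lists of genes of like level. The proliferation list had medians of -0.54 (-0.63 to -0.43) and -0.87 (-0.98 to -0.72) in CD4 T-like cells, percentiles 0 and 0, with 19 of 19 and 17 of 19 members lower, among them Stmn1, which regulates microtubules (2.20 and 2.46-fold lower), and Hmgb2 (1.34 and 1.53-fold lower). Cytotoxic effector genes lay higher there, at 1.16 (0.89 to 1.27) and 0.41 (0.20 to 0.60), percentiles 100 and 99.95, with 20 of 21 and 14 of 21 members higher. Examples were the chemokine Ccl4 (2.57 and 1.11-fold) and the granule protein Nkg7 (1.78 and 1.57-fold). Cd8a was higher in the class as well, at 13.7, 38.6, 29.7 and 43.0 CPM, so CD8 T cells or their RNA among CD4 T-like cells stay open as a source of the cytotoxic values. T cell exhaustion genes had medians of 0.48 (0.27 to 0.65) and 0.39 (0.27 to 0.96), percentiles 99.99 and 99.64, and 15 of 18 and 13 of 17 members higher. Among them Pdcd1, the gene of the inhibitory receptor PD-1, was 1.84 and 3.70-fold higher and Ctla4 1.10 and 1.20-fold lower, while Cd274, which encodes its ligand PD-L1, was 1.53 and 1.61-fold higher. Within anti-CTLA4 the cytotoxic median turned to -0.020 and the exhaustion median to -0.17 at 500 genes per barcode, the latter also to -0.060 with no barcodes left out as doublets. The naive and memory T cell list, with Klf2 1.86 and 1.13-fold and Il7r 0.992 and 1.20-fold, was at 0.10 (-0.0077 to 0.26) and -0.21 (-0.40 to 0.010), percentiles 61.8 and 10.4. Dissociation stress genes, early-response and heat shock genes that respond to tissue handling, were at 0.57 (0.53 to 0.67) and 0.40 (0.36 to 0.45), percentiles 100 and 99.99, with 16 of 16 and 14 of 16 members higher. Fosb is among them. Interferon gamma response genes were at 0.40 (0.26 to 0.56) and 0.32 (0.011 to 0.44), percentiles 99.85 and 99.2, with Gbp4, a guanylate binding protein, 1.32 and 1.43-fold and Irf1, an interferon-induced transcription factor, 1.24 and 1.34-fold higher. Type I interferon response genes, among them Isg15 (1.56 and 1.87-fold lower) and Ifi27l2a (1.54 and 1.78-fold lower), were at -0.10 (-0.34 to 0.033) and -0.42 (-0.58 to -0.20), percentiles 5.68 and 0.05, with 14 of 22 and 16 of 21 members lower. As a mean over cells the type I medians were -0.40 and -0.60, but within IgG the median was 0.030 at 500 genes per barcode and 0.032 with no barcodes left out as doublets.

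CD8 T-like and Treg-like cells could be compared less widely, as the control tumour with IgG held 1 CD8 T-like cell. In CD8 T-like cells within anti-CTLA4, most of them from TNK17 in the flavopiridol and TNK19 in the control tumour, the type I interferon list was at -1.85 (-2.10 to -1.53), percentile 0, with 18 of 19 members lower, such as Ifi27l2a (11.3-fold) and Isg15 (3.99-fold). T cell exhaustion genes were at -0.42 (-0.57 to -0.28) and naive and memory genes at -0.58 (-0.78 to -0.39), percentiles 0 and 0.21, with Pdcd1 1.55-fold lower. Cytotoxic effector genes were at 0.31 (0.15 to 0.35), percentile 99.66, and the granzyme gene Gzmb was 11.1-fold higher. Treg-like cells had Treg activation medians of -0.30 (-0.45 to -0.11) and 0.025 (-0.12 to 0.26), percentiles 0.08 and 75.2, with the costimulatory receptor gene Tnfrsf4 1.84 and 1.35-fold lower, Foxp3 0.962 and 1.52-fold and Ctla4 0.888 and 1.29-fold.

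In NK-like cells of flavopiridol tumours, type I interferon response genes were lower as a group and a few granzyme genes higher. The type I list stood at -0.56 (-0.69 to -0.48) and -1.06 (-1.19 to -0.91), percentiles 0 and 0, with 21 of 22 and 20 of 22 members lower. Isg15, an interferon-induced ubiquitin-like protein, was 1.75 and 2.48-fold lower, and Irf7, a transcription factor of the interferon response, was 1.94 and 2.62-fold lower, from 86.8 (80.9 to 93.0) to 44.8 (41.2 to 48.6) CPM within IgG. Other genes that led the lower side were the interferon-induced Ifi44 (1.87 and 1.62-fold), Xaf1 (1.56 and 2.22-fold) and Pyhin1 (1.58 and 1.70-fold), with BC094916 (1.62 and 1.76-fold) and Erdr1 (1.502 and 1.85-fold). Several of these also lead TNK13, an NK-like cluster with 1.73%, 1.14%, 1.04% and 1.07% of kept cells. On the higher side were Ifitm1, an interferon-inducible membrane protein (3.82 and 5.01-fold), AY036118 (1.83 and 3.16-fold), C1qtnf6 (1.78 and 2.15-fold) and Serpinb6a, a protease inhibitor (1.69 and 1.79-fold). Gzme, a granzyme (1.79 and 3.91-fold), and Ctsg, the protease cathepsin G (5.65 and 14.4-fold), also led TNK16, a cluster that took 63.7% of its cells from the flavopiridol tumour with anti-CTLA4. Of the Ctsg counts, 5 cells held 97.6%, 74.7%, 95.3% and 28.8%, and without the top 5 cells of each library Ctsg stood at 0.429, 25.1, 1.11 and 242 CPM, a wider gap than with them. The cytotoxic effector list was at -0.045 (-0.13 to -0.014) and -0.34 (-0.36 to -0.19), percentiles 38.1 and 0, with Gzmd 1.53 and 3.63-fold and Gzmf 1.29 and 3.39-fold but Gzma 0.843 and 0.964-fold. NK activation and inhibition genes were at -0.048 (-0.13 to -0.016) and -0.59 (-0.69 to -0.50), percentiles 23.2 and 0, with the activating receptor gene Ncr1 1.10 and 1.62-fold lower. Chemokines had medians of -0.81 (-0.84 to -0.23) and -0.44 (-0.82 to -0.26), percentiles 0 and 0.11, the latter turning to 0.62 with no barcodes left out as doublets. Ccl3, Ccl4 and Ccl5, which attract T cells and monocytes, were 1.84 and 3.03-fold, 1.75 and 2.79-fold and 1.12 and 2.92-fold lower. Interferon gamma response genes gave 0.12 (-0.047 to 0.20) and -0.20 (-0.52 to -0.11), percentiles 87.0 and 5.49, and proliferation genes 0.0032 (-0.063 to 0.039) and 0.18 (0.10 to 0.21), percentiles 49.5 and 99.84. Dissociation stress genes gave 0.31 (0.22 to 0.35) and -0.53 (-0.63 to -0.43), percentiles 100 and 0, with Junb 1.10 and 1.94-fold lower. Counting bounds of the 12 named folds lay within a factor of 1.18. NK-like cells came from 8 clusters, and the largest differed between libraries (TNK1, TNK2, TNK0 and TNK1, with 25.0%, 29.7%, 29.5% and 27.5% of the class).

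Neutrophil-like cells of flavopiridol tumours also had lower type I interferon genes, with medians of -0.62 (-0.69 to -0.47) and -1.01 (-1.13 to -0.96), percentiles 0 and 0, and 17 of 20 and 19 of 19 members lower. Isg15 was 1.31 and 2.49-fold lower and Rsad2, an antiviral enzyme, 1.61 and 2.10-fold lower. Named genes on the lower side were the adaptor Scimp (5.02 and 3.34-fold), the chemokine Cxcl1 (2.88 and 3.63-fold), the interferon-induced Ifit3 (2.79 and 3.38-fold), the transcription factor Batf (2.73 and 2.81-fold), the survival gene Bcl2a1a (2.79 and 2.36-fold) and Trim30c (2.28 and 2.81-fold). Without the top 5 cells of each library Cxcl1 stood at 217, 47.3, 421 and 84.4 CPM. Higher were Cpd, a carboxypeptidase (2.77 and 2.99-fold), the actin-binding Cnn2 (2.65 and 2.99-fold), the collagenase Mmp8 (2.60 and 2.72-fold), Lars2, the mitochondrial leucine tRNA ligase (2.59 and 2.82-fold), AY036118 (2.30 and 4.55-fold) and Rassf3 (2.49 and 2.30-fold). MHC class I presentation genes were lower, at -0.40 (-0.53 to -0.35) and -0.71 (-0.79 to -0.64), percentiles 0.01 and 0, in 16 of 16 and 16 of 16 members, among them Psmb8, a subunit of the immunoproteasome (1.88 and 2.03-fold). Interferon gamma response genes were at -0.23 (-0.35 to -0.020) and -0.79 (-1.01 to -0.67), percentiles 0.74 and 0, with Cxcl10 1.67 and 3.60-fold and Cd274 1.34 and 1.67-fold lower. The NF-kB inflammatory list was at -0.34 (-0.41 to -0.23) and -0.46 (-0.58 to -0.35), percentiles 0.03 and 0.03, with Ccl4 3.17 and 1.59-fold and Ccl3 2.02 and 1.25-fold lower. Neutrophil granule and activation genes gave 0.43 (0.19 to 0.50) and -0.046 (-0.32 to 0.016), percentiles 100 and 28.3, S100a8, which encodes a calcium-binding alarmin, being 1.67 and 1.47-fold higher. Glycolysis and hypoxia genes were at 0.079 (0.0039 to 0.15) and 0.86 (0.81 to 0.96), percentiles 43.9 and 100, the first of which took the other sign under both rescalings of totals (-0.0082 and -0.032), while Gapdh was 1.35 and 2.03-fold higher. Dissociation stress genes were at 0.12 (0.027 to 0.20) and 0.36 (0.29 to 0.44), percentiles 74.8 and 97.3. All genes of the class together had a median of 0.33 (log2) within anti-CTLA4, which rescaling brought to -0.015 or -0.0053. The largest cluster was cluster 11 except in the control tumour with anti-CTLA4, where cluster 12, led by Lcn2 and Rsad2, held 48.5% of the class. Cluster 12 held 378 of 1141, 206 of 776, 856 of 1766 and 182 of 1518 neutrophil-like cells. A different mix of clusters therefore stays open as a source of the differences in this class. With no barcodes left out as doublets, 750, 613, 844 and 1367 cells were named neutrophil-like, against 1141, 776, 1766 and 1518 in the main setting. The type I medians of that smaller set were -0.31 and -0.65. Under that setting the medians of interferon gamma genes (0.093) and NF-kB genes (0.089) within anti-CTLA4 and of MHC class I genes (0.096) within IgG turned above 0, and so did Bcl2a1a within anti-CTLA4 (0.49, log2). Counting bounds of the 12 named folds lay within a factor of 1.78.

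Macrophage-like cells of flavopiridol tumours had higher interferon gamma response and MHC class II genes under both antibodies. The interferon gamma list stood at 0.97 (0.85 to 1.05) and 0.95 (0.83 to 1.03), percentiles 100 and 100, with 18 of 18 and 18 of 18 members higher. Cxcl9, a chemokine that attracts activated T cells, was 5.78 and 1.76-fold higher, from 105 (97.7 to 113) to 607 (588 to 625) CPM within IgG, and Cxcl10 was 1.04 and 1.49-fold. MHC class II presentation genes were at 1.56 (1.42 to 1.72) and 0.50 (0.48 to 0.57), percentiles 100 and 99.76, with 10 of 10 and 9 of 10 members higher. Among them were the invariant chain gene Cd74 (3.16 and 1.51-fold) and the class II chain genes H2-Ab1 (3.48 and 1.52-fold) and H2-Eb1 (4.57 and 1.57-fold). Cxcl9, H2-Eb1, Cd74 and Serpina3g lead the cluster MM1, which held 0.164%, 0.477%, 0.231% and 1.88% of kept cells, and the largest macrophage-like clusters were MM6, MM2, MM0 and MM6, with 26.0%, 31.6%, 38.3% and 34.0% of the class. MHC class I genes were at 0.46 (0.42 to 0.52) and 0.15 (0.13 to 0.18), percentiles 100 and 95.9, with H2-K1 1.42 and 1.11-fold higher. Type I interferon genes were at -0.65 (-0.70 to -0.57) and 0.10 (-0.021 to 0.21) (the second -0.097 as a mean over cells), percentiles 0 and 67.7, with Isg15 1.88 and 1.35-fold lower. By the rule applied to this class after the data had been seen, the genes on the higher side were Hal, histidine ammonia lyase (2.66 and 7.55-fold), AA467197 (5.15 and 2.65-fold), and Serpina3g, a protease inhibitor (3.51 and 2.57-fold). They also held lipoprotein lipase Lpl (2.80 and 2.54-fold), the guanylate binding protein Gbp2 (2.24 and 2.32-fold) and the surface protein Ly6a (2.23 and 4.39-fold). Lower were Fcrls (4.83 and 13.7-fold), Gas6, a ligand of phagocytic receptors (3.01 and 2.32-fold), the chemokines Xcl1 (2.23 and 4.65-fold) and Ccl12 (2.79 and 2.22-fold), Ntpcr (1.99 and 2.87-fold) and Igfbp4 (1.97 and 2.70-fold). Fcrls and Ccl12 lead MM0. Xcl1 is a lymphocyte gene, and Ncr1, an NK receptor gene, was lower alongside it in macrophage-like cells, at 69.9, 37.4, 68.5 and 37.6 CPM, so NK cell RNA in the class stays open as its source. Cd3e, of the T cell receptor complex, stood at 34.9, 57.1, 19.5 and 25.9 CPM in macrophage-like cells against 245, 255, 272 and 257 in CD4 T-like cells.

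Other lists in macrophage-like cells are given within IgG and then within anti-CTLA4. Alternative macrophage activation genes were at -0.86 (-1.005 to -0.71) and 0.51 (0.43 to 0.63), percentiles 0 and 99.93, with Pf4, a chemokine, 0.411 and 1.65-fold and the mannose receptor Mrc1 0.514 and 0.991-fold. Myeloid suppressor genes were at -0.056 (-0.16 to 0.0033) and 0.92 (0.82 to 1.07), percentiles 39.9 and 100, Arg1, the enzyme arginase that depletes arginine, being 1.09 and 8.38-fold and Cd274 1.41 and 2.12-fold. Lipid handling and phagocytosis genes were at 0.044 (0.0080 to 0.17) and 0.79 (0.60 to 0.95), percentiles 73.0 and 100, with the cathepsin Ctsl 1.04 and 2.94-fold and Lgals3, a galectin, 1.26 and 2.33-fold, while the first median took the other sign under both rescalings of totals (-0.00030 and -0.021). Glycolysis and hypoxia genes were at 0.13 (0.082 to 0.16) and 0.65 (0.62 to 0.69), percentiles 97.7 and 100, with Pkm 0.980 and 1.54-fold. Chemokines were at -0.73 (-0.77 to -0.64) and 0.19 (0.15 to 0.22), percentiles 0 and 99.05, with the monocyte attractants Ccl2 and Ccl7 0.461 and 0.935-fold and 0.441 and 1.03-fold. NF-kB inflammatory genes gave -0.061 (-0.18 to 0.0022) and 0.27 (0.17 to 0.40), percentiles 26.1 and 97.4. Nucleic acid sensing genes gave 0.051 (-0.13 to 0.19) and 0.20 (0.041 to 0.35), percentiles 39.9 and 75.2, the latter median turning to -0.021 as a mean over cells. Dissociation stress genes gave 0.28 (0.25 to 0.32) and 0.26 (0.22 to 0.28), percentiles 100 and 99.5, with 13 of 16 and 13 of 16 members higher.

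The Ptprc-low clusters had higher interferon gamma response and MHC class I presentation genes in flavopiridol tumours. The interferon gamma list was at 1.12 (0.96 to 1.32) and 1.03 (0.91 to 1.21), percentiles 100 and 100, with 15 of 16 and 17 of 18 members higher, among them Ly6a (1.92 and 1.84-fold) and Irf1 (1.60 and 1.33-fold), while Cxcl10 was 0.684 and 1.63-fold. MHC class I genes were at 0.56 (0.46 to 0.60) and 0.61 (0.53 to 0.66), percentiles 100 and 100, with 16 of 17 and 17 of 17 members higher, such as the heavy chain genes H2-K1 (1.303 and 1.44-fold) and H2-D1 (1.17 and 1.28-fold). Chosen by the same rule after the data had been seen, the named genes on the higher side were the guanylate binding proteins Gbp2b (5.24 and 3.38-fold), Gbp2 (3.87 and 3.28-fold, from 26.4 (25.0 to 27.8) to 102 (98.9 to 105) CPM within IgG), Gbp7 (2.49 and 2.54-fold) and Gbp3 (2.37 and 2.49-fold). With them came the peptide transporter Tap1 (2.41 and 2.03-fold) and the nucleic acid sensor Zbp1 (1.96 and 2.06-fold). Lower were the histone gene Hist1h2ae (1.94 and 1.80-fold), Ifi27l2a (2.12 and 1.69-fold), Lsm7 (1.51 and 1.69-fold), Hmgn2 (1.49 and 1.67-fold), the peroxidase Prdx3 (1.45 and 1.55-fold) and Mgst3 (1.44 and 1.66-fold). Type I interferon genes were at -0.30 (-0.34 to -0.24) and 0.18 (0.14 to 0.24), percentiles 0 and 65.8, with Irf7 0.541 and 1.13-fold. Nucleic acid sensing genes were at 0.35 (0.26 to 0.42) and 0.23 (0.17 to 0.33), percentiles 99.6 and 63.6, with Samhd1 1.49 and 1.88-fold higher. Dissociation stress genes were at -0.015 (-0.029 to 0.064) and -0.13 (-0.16 to -0.081), percentiles 50.8 and 12.9. Proliferation genes were at 0.089 (0.041 to 0.11) and 0.087 (0.074 to 0.16), percentiles 90.6 and 92.1, values that took the other sign under both rescalings (-0.033 and -0.031 within IgG, -0.025 and -0.056 within anti-CTLA4), as the median of all genes in these clusters was itself 0.12 and 0.15. Cluster 1, led by Nppb, Igfbp6 and Rarres1, was the largest of the 3 in every library. Conventional dendritic-like cells likewise had interferon gamma medians of 0.42 (0.30 to 0.64) and 0.71 (0.53 to 0.85), percentiles 99.99 and 100, with Cxcl9 5.41 and 1.46-fold. Type I medians there were -0.71 (-0.86 to -0.55) and -0.46 (-0.56 to -0.23), percentiles 0 and 0, with Irf7 1.81 and 2.25-fold lower. Their MHC class II genes were at 0.051 (-0.0024 to 0.083) and 0.030 (-0.045 to 0.060), percentiles 91.3 and 72.0. Co-stimulation genes there were at 0.18 (-0.082 to 0.45) and 0.11 (-0.23 to 0.26), percentiles 77.2 and 45.0, with Cd86 1.49 and 1.07-fold.

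**Figure D3:**
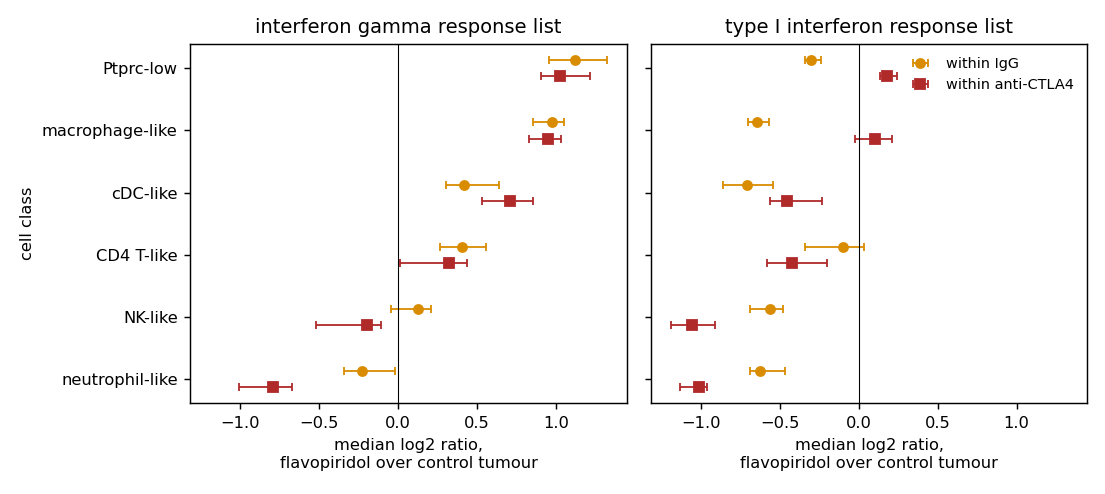
Median log2 ratio of flavopiridol over control tumour for the interferon gamma and type I interferon response lists in 6 classes, with points for the comparison within IgG and within anti-CTLA4 and bars for the counting interval of the median. Ptprc-low and macrophage-like values of the interferon gamma list lay between 0.95 and 1.12, while the type I list lay below 0 in NK-like, neutrophil-like and conventional dendritic-like cells.

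Some signals differed between the libraries in nearly every class at once. The share of UMIs from mitochondrially encoded genes was higher in flavopiridol tumours in 13 of 13 classes under both antibodies, by 1.21-fold to 1.79-fold within IgG and 1.24-fold to 2.13-fold within anti-CTLA4. AY036118, a transcript named in 3 classes above, was higher in 12 of 13 classes under both, and Lars2, named in neutrophil-like cells, in 12 and 13 of 13. A gene named in 1 class may be shared. In other classes, Ifi27l2a (Ptprc-low) was lower in 11 of 12 and Emp1 (CD4 T-like) higher in 8 of 8 under both. Zbp1 (Ptprc-low) was higher in only 4 and 5 of 11. With anti-CTLA4 against IgG, Lars2 was higher in 0 of 13 classes in both kinds of tumour (median ratios 0.662 and 0.598). AY036118 and the mitochondrial share were higher in 0 of 13 in control tumours (0.474 and 0.847). In flavopiridol tumours they were higher in 8 and 3 of 13 (1.03 and 0.948).

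The second comparison asked how CTLA4 blockade differed from IgG in control and in flavopiridol tumours. CD8 T-like cells were higher with anti-CTLA4 in both kinds of tumour, from 1 cell to 622 cells in control tumours, a ratio of 550.2 (98.4 to 21766), and from 90 to 279 in flavopiridol tumours, a ratio of 2.67 (2.10 to 3.43). Treg-like cells were lower in both, with ratios of 0.660 (0.502 to 0.865) in control and 0.353 (0.285 to 0.435) in flavopiridol tumours, and made up 19.9%, 15.2%, 18.7% and 9.39% of CD4 T-like and Treg-like cells together. CD4 T-like cells, with ratios of 0.712 (0.625 to 0.811) and 0.611 (0.568 to 0.658), and gamma-delta T-like cells, with 0.538 (0.409 to 0.704) and 0.701 (0.621 to 0.792), were lower as well. Named T-like cells together were higher in control tumours, 1.36 (1.24 to 1.48), through the CD8 T-like class alone. In flavopiridol tumours they were lower, 0.669 (0.632 to 0.708). Among myeloid classes, monocyte-like cells had ratios of 0.349 (0.288 to 0.422) and 0.490 (0.407 to 0.587), conventional dendritic-like cells 0.361 (0.280 to 0.463) and 0.683 (0.499 to 0.933), and macrophage-like cells 0.9496 (0.842 to 1.07) and 1.95 (1.73 to 2.20). Neutrophil-like ratios were 1.37 (1.27 to 1.48) and 1.69 (1.55 to 1.84). NK-like ratios were 0.901 (0.830 to 0.977) and 1.26 (1.18 to 1.35), B-like ratios 1.19 (0.892 to 1.58) and 0.520 (0.366 to 0.732), and those of Ptprc-low clusters 0.933 (0.863 to 1.01) and 1.16 (1.07 to 1.27). Mast or basophil-like ratios were 0.262 (0.153 to 0.431) and 0.439 (0.268 to 0.705), plasmacytoid dendritic-like 0.700 (0.363 to 1.33) and 0.314 (0.148 to 0.623), and migratory dendritic-like 0.553 (0.224 to 1.296) and 0.945 (0.5001 to 1.80). With libraries clustered on their own, the CD8 T-like ratios were 2.56 and 0.599, and with each cell named by its own markers 14.7 and 1.15, while the ratio of CD4 T-like cells in control tumours turned to 1.01 at a finer clustering. With libraries clustered on their own the CD4 T-like ratios were 0.979 and 0.113, the macrophage-like ratio in control tumours 1.67 and the neutrophil-like ratio in flavopiridol tumours 1.09. In flavopiridol tumours the monocyte-like ratio was 0.944 at 500 genes per barcode and 0.791 with each cell named by its own markers, which put the Treg-like ratio at 0.569. In control tumours the neutrophil-like ratio was below 1 at 10% mitochondrial UMIs (0.939), with no barcodes left out as doublets (0.987) and with libraries clustered on their own (0.781).

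The genes named in CD4 T-like and NK-like cells differed with anti-CTLA4 by less than 2-fold in flavopiridol tumours. Folds are given in control and then in flavopiridol tumours. CD4 T-like cells had higher Jun, an early-response transcription factor (1.54 and 1.38-fold), Ly6a (1.82 and 1.37-fold) and the adhesion protein Emb (1.58 and 1.36-fold). Klrd1, an NK receptor gene, was also higher (2.66 and 1.37-fold, but -0.62 and -0.66 (log2) in flavopiridol tumours at 500 genes per barcode and with no barcodes left out as doublets). Lower there were the integrin Itgb1 (1.57 and 1.77-fold), the chemokine receptor Cxcr4 (1.83 and 1.56-fold), the transcription factor Maf (1.83 and 1.52-fold) and Rnf213 (1.58 and 1.48-fold). Cytotoxic effector genes of CD4 T-like cells were at 0.71 (0.55 to 0.87) and -0.032 (-0.21 to 0.19), percentiles 100 and 51.9, while Cd8a there went from 13.7 to 29.7 CPM in control tumours and from 38.6 to 43.0 in flavopiridol tumours, so the same source stays open. Exhaustion genes were at -0.088 (-0.41 to 0.13) and -0.076 (-0.21 to 0.12), percentiles 16.6 and 27.8. Naive and memory genes were at -0.10 (-0.23 to 0.092) and -0.52 (-0.64 to -0.35), percentiles 6.34 and 0. Ctsw, a cathepsin of cytotoxic cells, was 1.79 and 0.763-fold and Nkg7 1.49 and 1.32-fold. In CD8 T-like cells of flavopiridol tumours, the only arm with more than 1 such cell in both libraries, type I interferon genes were at -1.77 (-2.11 to -1.302), exhaustion genes at -0.43 (-0.55 to -0.24), naive and memory genes at -0.98 (-1.36 to -0.57) and cytotoxic genes at 0.057 (-0.067 to 0.13), the last turning to -0.42 at 500 genes per barcode. Their percentiles were 0, 0, 0 and 45.0. Treg activation genes in Treg-like cells were at -0.29 (-0.51 to -0.12) and 0.038 (-0.071 to 0.16), percentiles 0.44 and 81.9, with Ctla4 0.585 and 0.850-fold and Foxp3 0.817 and 1.29-fold. NK-like cells had higher Ifitm1 (1.34 and 1.76-fold), Serpinb6a (1.33 and 1.41-fold), the phosphatase Ptp4a3 (1.32 and 1.38-fold) and the kinase Dapk2 (1.24 and 1.24-fold). The corepressor Tle3 (1.65 and 1.68-fold), Lars2 (1.497 and 1.68-fold), the metalloproteinase Adamts14 (1.71 and 1.49-fold) and the cohesin subunit Rad21 (1.53 and 1.48-fold) were lower, Lars2 as in all 13 classes. Type I interferon genes in NK-like cells were at -0.11 (-0.22 to 0.014) and -0.56 (-0.62 to -0.42), percentiles 14.3 and 0, with 12 of 22 and 22 of 22 members lower. NK activation and inhibition genes were at 0.11 (-0.0033 to 0.18) and -0.37 (-0.42 to -0.26), percentiles 99.1 and 0, where Ccl5 was 1.13 and 0.430-fold. Their cytotoxic list was at -0.031 (-0.042 to -0.0039) and -0.26 (-0.29 to -0.21), percentiles 20.4 and 0, the first value turning to 0.021 as a mean over cells and to 0.00089 under median-of-ratios scaling, and the median of all their genes was -0.14 in flavopiridol tumours. Counting bounds of the named folds lay within factors of 1.38 in CD4 T-like and 1.17 in NK-like cells.

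In myeloid classes, neutrophil-like cells had higher interferon gamma response and MHC class I genes with anti-CTLA4. The interferon gamma list was at 0.78 (0.68 to 0.91) and 0.29 (0.15 to 0.46), percentiles 100 and 97.2. The MHC class I list was at 0.70 (0.63 to 0.79) and 0.43 (0.37 to 0.57), percentiles 100 and 99.96, with Irf1 1.59 and 1.23-fold and Psmb8 1.86 and 1.72-fold. Type I genes were at 0.52 (0.39 to 0.65) and -0.055 (-0.19 to 0.22), percentiles 100 and 15.1, the second being 0.55 with no barcodes left out as doublets. Scimp (3.67 and 5.52-fold), the cytokine Ltb (2.61 and 2.40-fold), and the interferon-induced Ifi27l2a (5.78 and 2.18-fold) and Oasl2 (2.51 and 2.14-fold) were higher. Without the top 5 cells of each library Scimp stood at 43.9, 6.14, 181 and 51.8 CPM. Lower were Csf3, the granulocyte growth factor (4.81 and 3.22-fold), Malt1, an NF-kB activator (3.57 and 3.13-fold), Batf (2.47 and 2.54-fold) and the iron-binding lipocalin Lcn2 (3.17 and 2.43-fold). However, Csf3 in flavopiridol tumours (0.19, log2) and Batf in control tumours (0.31) were higher with no barcodes left out as doublets. Glycolysis and hypoxia genes were at -0.92 (-0.997 to -0.77) and -0.013 (-0.091 to 0.052), percentiles 0 and 26.8, with Ldha 0.515 and 0.822-fold. NF-kB genes were at -0.28 (-0.34 to -0.26) and -0.39 (-0.44 to -0.26), percentiles 0.1 and 0, the second value turning to 0.17 with no barcodes left out as doublets. Granule and activation genes were at 0.092 (0.052 to 0.21) and -0.071 (-0.11 to -0.058), percentiles 75.8 and 16.1, values close to 0 that took the other sign with no barcodes left out as doublets (-0.14 and 0.071) and, in control tumours, as a mean over cells (-0.019). Macrophage-like cells, from the clusters named above, had higher interferon gamma genes, at 0.17 (0.12 to 0.30) and 0.36 (0.29 to 0.46), percentiles 99.54 and 100, with Cxcl9 5.66 and 1.73-fold, although the value in control tumours was -0.015 at 500 genes per barcode. Named after the data had been seen, Ckb, creatine kinase (2.24 and 2.10-fold), the Fc receptor Fcgr4 (2.35 and 1.78-fold), the inhibitory receptor Lair1 (2.09 and 1.75-fold) and Serpina3g (2.38 and 1.75-fold) were higher. Satb1 (2.99 and 2.68-fold), Ets1 (2.10 and 2.35-fold), Gimap5 (1.83 and 2.17-fold) and Gimap3 (1.99 and 1.83-fold), all genes of lymphocytes, were lower. Cd3e was lower in the class too, from 34.9 to 19.5 CPM in control and from 57.1 to 25.9 in flavopiridol tumours, so lymphocyte RNA in the class stays open as the source of these 4. Alternative activation genes were at -1.22 (-1.26 to -1.18) and 0.22 (0.12 to 0.29), percentiles 0 and 99.88, with Pf4 0.378 and 1.52-fold, and the second value turned to -0.10 with no barcodes left out as doublets. Myeloid suppressor genes were at -0.73 (-0.79 to -0.68) and 0.21 (0.0077 to 0.42), percentiles 0 and 99.97, with Arg1 0.333 and 2.56-fold. Chemokines were at -0.27 (-0.31 to -0.25) and 0.35 (0.30 to 0.40), percentiles 0.02 and 99.99, and NF-kB genes at -0.52 (-0.65 to -0.39) and -0.22 (-0.28 to -0.11), percentiles 0 and 1.36. Lipid handling genes were at -0.18 (-0.24 to -0.056) and 0.34 (0.31 to 0.49), percentiles 8.08 and 100, the first turning to 0.0083 under median-of-ratios scaling. The median of all macrophage-like genes was -0.16 and -0.14, so list values stand against a shift of that size.

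The Ptprc-low clusters had higher interferon gamma and MHC class I genes and lower proliferation genes with anti-CTLA4 in both kinds of tumour. Interferon gamma genes were at 0.78 (0.66 to 0.89) and 0.76 (0.65 to 0.78), percentiles 100 and 100, with 15 of 16 and 16 of 16 members higher. MHC class I genes were at 0.24 (0.22 to 0.27) and 0.32 (0.29 to 0.35), percentiles 100 and 100. Proliferation genes were at -0.28 (-0.31 to -0.27) and -0.19 (-0.22 to -0.17), percentiles 0 and 0, with 19 of 19 and 19 of 19 members lower and Tuba1b, a tubulin, 1.36 and 1.16-fold lower. Cluster 4, led by the cell cycle genes Ube2c, Pbk and Cenpf, held 386 of 1266, 272 of 886, 335 of 1335 and 323 of 1196 Ptprc-low cells, a lower part with anti-CTLA4, so a different mix of clusters stays open as the source. Named after the data had been seen, Ly6a (1.95 and 1.88-fold), Cryab (2.05 and 1.63-fold), Mt1 (1.504 and 1.65-fold) and Psmb9 (2.30 and 1.502-fold) were higher. Mgp (1.60 and 1.46-fold), Dpysl3 (1.61 and 1.38-fold), Itgb5 (1.36 and 1.40-fold) and Ddx3x (1.41 and 1.34-fold) were lower. Mgp and Itgb5 lead cluster 19 (273, 169, 241 and 184 cells, also a lower part) and Cryab cluster 1. The mix stays open as their source too. The median of all genes in the class was -0.12 in control and -0.091 in flavopiridol tumours, so list values stand against such shifts. Conventional dendritic-like cells had co-stimulation medians of -0.29 (-0.71 to -0.00042) and -0.36 (-0.76 to -0.17), percentiles 5.05 and 1.76, with the activation marker Cd83 0.616 and 0.586-fold.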

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

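The tests of naming, depth and single-library expansion for CD8 T-like cells and of scaling for macrophage-like cells were chosen only after those results were seen. Every result in this paragraph stood out because the same contrast went opposite ways in the 2 arms, a difference that was not tested, as each group held 1 library. Among shares, the log2 ratio of flavopiridol to control within anti-CTLA4 minus that within IgG was -7.68 for CD8 T-like cells, from 1 cell in the control tumour with IgG, and 1.04 for macrophage-like cells. For anti-CTLA4 against IgG, the log2 ratio in flavopiridol minus that in control tumours was 0.487 for NK-like cells. It was -1.02 for all named T-like cells, which rose in control tumours through CD8 T-like cells alone. Of the list medians, the flavopiridol effect within anti-CTLA4 minus that within IgG was 0.49 for type I interferon genes in Ptprc-low clusters, 1.37 for alternative activation genes and 0.91 for chemokines in macrophage-like cells, and -0.84 for dissociation stress genes in NK-like cells. The anti-CTLA4 effect in flavopiridol tumours minus that in control tumours was 0.94 for myeloid suppressor genes, 1.45 for alternative activation genes, 0.51 for lipid handling genes and 0.62 for chemokines in macrophage-like cells, and -0.16 for granule genes in neutrophil-like cells.

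CD8 T-like cells took a higher share in flavopiridol tumours within IgG and a lower one within anti-CTLA4. Naming alone is argued against, since Cd8a over all T clusters had ratios of 4.91 (4.05 to 5.996) and 0.484 (0.464 to 0.506), the same ways. Depth per cell is argued against too, as thinned shares of T-cluster cells with a Cd8a or Cd8b1 UMI had ratios of 2.17 (1.56 to 3.06) and 0.311 (0.271 to 0.357). An expansion in the animals of 1 library stays open, as animals cannot be told apart. Only cluster TNK19 was lower within anti-CTLA4, and 88.3% of it came from the control tumour there. A response to CTLA4 blockade that differs between control and flavopiridol tumours also stays open and untested.

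Alternative macrophage activation genes were lower in macrophage-like cells of flavopiridol tumours within IgG and higher within anti-CTLA4. Scaling is argued against, since the medians nearest to 0 under 2 other scalings were -0.91 and 0.42. Within IgG a different mix is argued against as the whole cause only among 5 clusters with at least 20 cells in every library. Their median was -0.92 (from -1.34 to 0.32, with MM2 the other way). MM0, MM1, MM4 and MM13 were not compared. Within anti-CTLA4 a different mix cannot be told apart from a difference inside clusters, as that median was 0.19 (from -0.16 to 0.90) against a class value of 0.51. An effect of the treated tumour cells on macrophages stays open and untested.

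Interferon gamma genes were higher in Ptprc-low clusters and type I interferon genes lower in NK-like cells of flavopiridol tumours, the same way in both arms. RNA of immune cells in Ptprc-low barcodes is argued against, since it would have to make up 19.9% of their RNA in the arm that needs less, or 5.55% within IgG and 5.15% within anti-CTLA4 if all came from the highest class, and abundant immune genes such as Tyrobp and Laptm5 allow at most 1.05%. A different mix of NK-like clusters is argued against as the whole cause, since the type I median was -0.27 or lower in each of the 3 largest clusters and both arms, although part of the class values of -0.56 and -1.06 may come from the mix. A loss of type I RNA that follows the mitochondrial share from cell to cell is argued against. Control NK-like cells with the higher mitochondrial share had type I medians that were 0.18 and 0.31 higher, not lower. This split within libraries cannot decide on a quality difference between whole libraries. The mitochondrial share was higher in 13 of 13 classes of flavopiridol tumours under both antibodies, with 1 library per group. Whether the Ptprc-low clusters hold tumour cells was not tested. A response to the treated tumour cells, or a difference in them, remains a hypothesis, found and tested on the same data.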

How the results depend on the processing

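Tests chosen only after the results were seen were the denominator without Ptprc-low and fibroblast-like clusters, the neutrophil-like share without cluster 12, and the named genes of macrophage-like cells and Ptprc-low clusters. Each alternative altered 1 choice, except that naming each cell by its own markers also used a minimum score of 0.25 in place of 0.35 and no vetting of clusters, and clustering each library on its own also scaled markers within the library. No paired analysis was made, and values are given within each antibody and each kind of tumour. In the alternatives, all named T-like ratios also count in T cells given no T class, which the main setting did not have. Of 522 alternative values for 60 ratios of shares, 424 stayed within the counting interval of the ratio, 85 lay outside it on the same side or without a call, and 13 crossed to the other side of 1. For 142 list medians the counts were 710, 258 and 25 of 993, and for 200 gene ratios 646, 346 and 8 of 1000. Values below are those that crossed and, for the class shares and the leading lists, those outside the interval. The cause was not tested for any of them. Flavopiridol against control is given within IgG and within anti-CTLA4, and anti-CTLA4 against IgG in control and in flavopiridol tumours, in that order.

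At Leiden resolution 0.5, CD4 T-like ratios were 2.51, 3.00, 0.551 and 0.658 in the order above, and all named T-like ratios were 0.713 in flavopiridol tumours. Macrophage-like ratios were 1.004 within anti-CTLA4 and 1.53 in flavopiridol tumours, and monocyte-like ratios were 0.958 within IgG. At Leiden resolution 1.5, CD4 T-like ratios were 1.93 within anti-CTLA4, reversed to 1.01 in control tumours and 0.685 in flavopiridol tumours, and macrophage-like ratios were 1.10 in control tumours. Monocyte-like ratios were 0.666 in flavopiridol tumours. With at most 10% mitochondrial UMIs, CD4 T-like ratios were 3.38 within IgG, and monocyte-like ratios were 0.462 in control tumours. Neutrophil-like ratios were 0.747 within IgG, reversed to 1.52 within anti-CTLA4, reversed to 0.939 in control tumours and 1.91 in flavopiridol tumours. With at least 500 genes per barcode, all named T-like ratios were 1.32 within anti-CTLA4, and NK-like ratios were 1.28 within anti-CTLA4. Macrophage-like ratios were 0.537 within IgG, reversed to 0.748 within anti-CTLA4, 1.15 in control tumours and 1.60 in flavopiridol tumours, and monocyte-like ratios were 1.44 within anti-CTLA4, 0.509 in control tumours and 0.944 in flavopiridol tumours. Neutrophil-like ratios were 0.771 within IgG and 0.912 within anti-CTLA4. With no barcodes left out as doublets, CD4 T-like ratios were 3.40 within IgG and 2.78 within anti-CTLA4, and macrophage-like ratios were 0.557 within IgG, reversed to 0.980 within anti-CTLA4, 1.32 in control tumours and 2.32 in flavopiridol tumours. Neutrophil-like ratios were 0.694 within IgG, reversed to 1.34 within anti-CTLA4, reversed to 0.987 in control tumours and 1.90 in flavopiridol tumours. Here and at 10% mitochondrial UMIs the naming of clusters changed too, as given above.

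Naming each cell by its own markers, CD4 T-like ratios were 2.13 within IgG and 0.571 in control tumours, and CD8 T-like ratios were 5.41 within IgG, 14.7 in control tumours and 1.15 in flavopiridol tumours. All named T-like ratios were 2.46 within IgG and 1.18 in control tumours, and Treg-like ratios were 1.88 within anti-CTLA4 and 0.569 in flavopiridol tumours. Macrophage-like ratios were 1.07 within anti-CTLA4, 1.28 in control tumours and 2.42 in flavopiridol tumours, and monocyte-like ratios were 0.481 in control tumours and 0.791 in flavopiridol tumours. Conventional dendritic-like ratios were 0.660 within IgG, reversed to 1.01 within anti-CTLA4 and 0.496 in control tumours. Clustering each library on its own, CD4 T-like ratios were reversed to 0.895 within IgG, reversed to 0.103 within anti-CTLA4, 0.979 in control tumours and 0.113 in flavopiridol tumours, and CD8 T-like ratios were 1.74 within IgG, 2.56 in control tumours and reversed to 0.599 in flavopiridol tumours. All named T-like ratios were 2.32 within IgG, 1.33 within anti-CTLA4 and 1.18 in control tumours, and gamma-delta T-like ratios were 2.87 within IgG and 0.404 in control tumours. Macrophage-like ratios were 0.936 within IgG, 1.14 within anti-CTLA4 and 1.67 in control tumours, and monocyte-like ratios were 0.938 within IgG and 0.456 in control tumours. Neutrophil-like ratios were 0.832 within anti-CTLA4, reversed to 0.781 in control tumours and 1.09 in flavopiridol tumours, and conventional dendritic-like ratios were 0.631 within IgG. Ptprc-low ratios were 0.534 within IgG. Over the kept cells that were not neutrophil-like, CD4 T-like ratios were 0.667 in flavopiridol tumours, and all named T-like ratios were 2.68 within IgG, 1.32 within anti-CTLA4 and 0.731 in flavopiridol tumours. NK-like ratios were 0.898, 1.26, 0.984 and 1.38 in the order above, and Ptprc-low ratios were 0.548 within IgG, 0.684 within anti-CTLA4 and 1.02 in control tumours. Leaving Ptprc-low and fibroblast-like clusters out of the denominator, ratios within IgG were 2.59 for CD4 T-like and 2.65 for all named T-like cells. They were 0.889 for NK-like and 0.528 for neutrophil-like cells. Leaving out neutrophil-like cluster 12, neutrophil-like ratios were 0.641 within IgG, reversed to 1.23 within anti-CTLA4, 1.05 in control tumours and 2.02 in flavopiridol tumours.

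At 500 genes per barcode, CD4 T-like medians within anti-CTLA4 were reversed to -0.17 for T cell exhaustion and -0.020 for cytotoxic effector genes. NK-like type I interferon medians were -0.41 in flavopiridol tumours, and macrophage-like MHC class II medians were 0.40 within anti-CTLA4. Macrophage-like interferon gamma medians were 0.85 within IgG and reversed to -0.015 in control tumours, and neutrophil-like type I interferon medians were 0.77 in control tumours. With no barcodes left out as doublets, medians within anti-CTLA4 were reversed to -0.060 for CD4 T-like exhaustion and 0.62 for NK-like chemokine genes. NK-like type I interferon medians were -0.39 in flavopiridol tumours, and macrophage-like MHC class II medians were 1.91 within IgG. Macrophage-like alternative activation medians were reversed to -0.10 in flavopiridol tumours, and interferon gamma medians were 1.05 within anti-CTLA4. Neutrophil-like medians were reversed to 0.10 within IgG for MHC class I and 0.093 within anti-CTLA4 for interferon gamma genes. For NF-kB they were reversed to 0.089 within anti-CTLA4 and 0.17 in flavopiridol tumours. For granule and activation genes they were reversed to -0.14 in control and 0.071 in flavopiridol tumours. Neutrophil-like type I interferon medians were -0.31, -0.65, 0.72 and 0.55 in the order above, and Ptprc-low interferon gamma medians were 0.85 within anti-CTLA4 and 0.65 in flavopiridol tumours. Under TMM scaling, NK-like type I interferon medians were -0.40 in flavopiridol tumours, and macrophage-like MHC class II medians were 0.45 within anti-CTLA4. Macrophage-like interferon gamma medians were 0.34 in control and 0.52 in flavopiridol tumours, and lipid handling and phagocytosis medians reversed to -0.00030 within IgG. Neutrophil-like glycolysis and hypoxia medians were reversed to -0.0082 within IgG, and neutrophil-like type I interferon medians were -0.71 within IgG, -1.36 within anti-CTLA4 and 0.72 in control tumours. Ptprc-low MHC class I medians were 0.43, 0.49, 0.34 and 0.43 in the order above, and Ptprc-low interferon gamma medians were 0.87 in flavopiridol tumours. Ptprc-low proliferation medians were reversed to -0.033 within IgG and reversed to -0.025 within anti-CTLA4. Under median-of-ratios scaling, NK-like cytotoxic effector medians were reversed to 0.00089 in control tumours, and NK-like type I interferon medians were -0.41 in flavopiridol tumours. Macrophage-like MHC class II medians were 0.42 within anti-CTLA4, and macrophage-like interferon gamma medians were 0.36 in control tumours and 0.53 in flavopiridol tumours. Macrophage-like lipid handling medians were reversed to -0.021 within IgG and 0.0083 in control tumours, and neutrophil-like glycolysis and hypoxia medians to -0.032 within IgG. Neutrophil-like type I interferon medians were -0.74 within IgG and -1.35 within anti-CTLA4, and Ptprc-low MHC class I medians were 0.44, 0.46, 0.36 and 0.42 in the order above. Ptprc-low interferon gamma medians were 0.88 within anti-CTLA4, 0.90 in control and 0.86 in flavopiridol tumours. Proliferation medians there were reversed to -0.031 within IgG and -0.056 within anti-CTLA4.

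As means over cells, CD4 T-like type I interferon medians were -0.40 within IgG and -0.60 within anti-CTLA4, and NK-like cytotoxic effector medians were reversed to 0.021 in control tumours. NK-like type I interferon medians were -0.76 within anti-CTLA4, -0.30 in control tumours and -0.32 in flavopiridol tumours, and macrophage-like MHC class II medians were 1.12 within IgG and 0.32 within anti-CTLA4. Macrophage-like interferon gamma medians were 0.76 within IgG, 0.73 within anti-CTLA4 and 0.28 in flavopiridol tumours. Nucleic acid sensing medians there were reversed to -0.021 within anti-CTLA4. Neutrophil-like neutrophil granule and activation medians were reversed to -0.019 in control tumours, and Ptprc-low MHC class I medians were 0.45 within anti-CTLA4 and 0.21 in control tumours. Ptprc-low interferon gamma medians were 0.91 within IgG. With members of 1 summed count or more, neutrophil-like type I interferon medians were 0.26 in control tumours. With members of 100 summed counts or more, macrophage-like MHC class II medians were 0.59 within anti-CTLA4, and neutrophil-like type I interferon medians were 0.71 in control tumours.

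At 500 genes per barcode, CD4 T-like Klrd1 was reversed to -0.62 in flavopiridol tumours and Nrgn to -0.37 within IgG and -0.92 within anti-CTLA4. With no barcodes left out as doublets, CD4 T-like Klrd1 was reversed to -0.66 in flavopiridol tumours and Nrgn to -1.51 within anti-CTLA4. Neutrophil-like Batf was reversed to 0.31 in control tumours, Bcl2a1a to 0.49 within anti-CTLA4 and Csf3 to 0.19 in flavopiridol tumours.

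Over all alternatives run, flavopiridol ratios of gamma-delta T-like cells lay between 2.87 and 3.96 within IgG and between 3.82 and 5.07 within anti-CTLA4. Those of all T-like cells, with T cells given no T class counted in, lay between 2.32 and 3.16 and between 1.32 and 1.45. The interferon gamma medians of the Ptprc-low clusters lay between 0.91 and 1.18 and between 0.85 and 1.08, and the type I medians of NK-like cells between -0.64 and -0.53 and between -1.10 and -0.76. Clustering each library on its own gave no conventional dendritic-like, Ptprc-low or plasmacytoid dendritic-like cells in the flavopiridol tumour with anti-CTLA4 and no migratory dendritic-like cells in any library, so those ratios have no value. In that tumour 1196 cells were then named fibroblast-like, as many as were Ptprc-low with the libraries clustered together, so the missing Ptprc-low value reflects naming. Naming each cell by its own markers gave no Ptprc-low class. Depth limits the classes unevenly, as given above for neutrophil-like cells. The control tumour with IgG held 1 CD8 T-like cell.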

Other observations

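Xist, the RNA of the inactive X chromosome, stood at 807, 991, 723 and 742 CPM in NK-like cells and at 3.63, 7.02, 2.67 and 5.17 CPM in the Ptprc-low clusters. Of the Y-linked genes of the sex-linked check, Ddx3y and Eif2s3y had 1 and 0 counts over all kept cells, and Kdm5d and Uty at most 3 in a library. No explanation of these values was tested.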
